A study of Mus musculus with 13 samples.

How the data were processed

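RNA of Paneth cells and intestinal stem cells was sequenced on an Illumina HiSeq instrument, per the labels. RNA was prepared with an RNeasy kit, stem cell libraries by standard Illumina protocols and Paneth libraries with a Clontech SMARTer pico kit. The labels speak of triplicates, while 4 young Paneth libraries were deposited; all 4 were used, as 4, 3, 3 and 3 libraries of young Paneth, aged Paneth, young stem and aged stem cells. The numbers of the replicates do not state that a pair of libraries came from the same mouse or day.

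Each library has a table of 36186 rows with a gene ID, an Entrez ID, a symbol and a value. The authors deposited these values under the column name FPKM, but in their behaviour they are expected counts (reads per gene, with shared reads split into fractions). Between 69.77% and 77.49% of values under 20 lie within 0.001 of a whole number. Expressed in units of 1/60, 93.03% to 95.4% of them lie within 0.01 units of a whole number. Scaling by length and depth would not leave such shares. The processing notes name the mm10 genome and DESeq without a role or version. The aligner, the counting tool and the annotation are not given in the sources used here. Rows of the same Entrez ID were summed to 35791 genes and the sums rounded to whole numbers. A spreadsheet had turned 27 symbols into dates, and these were restored by Entrez ID. Positions are those of the GRCm38 gene table, which held 32961 of the Entrez IDs. No genes encoded by the mitochondrial genome are in the files, so the list of these could not be tested.

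Library totals and the share of the 3 loci with most reads are given with the results. Counting error is small beside the spread between libraries: the chi-square per gene between libraries of the same group lay between 15 and 99 over 15 pairs.

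Age was compared within each cell type in its own fit, aged minus young. A model of all 13 libraries with a mean per group gave the difference of the age changes and Paneth minus stem at each age. Tests were edgeR 4.0.16 quasi-likelihood tests (TMM scaling, filterByExpr, robust dispersion) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The biological coefficient of variation was 0.246 in stem, 0.406 in Paneth and 0.339 in all libraries. CPM are TMM-scaled within the fit of the comparison, and over all 13 libraries for the sex-linked genes. ± is the SD of libraries for CPM and shares. For log2 changes it is an approximate SE, the absolute log2 change divided by the square root of the quasi-likelihood F. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists with at least 5 tested members, and members were counted as passing over all genes and when adjusted over the list alone. Comparisons, gene lists, alternatives and the rule for naming genes were written before the data were examined. The 37 lists cover Wnt signalling, stem cells, cell types of the gut, immune and stromal cells, stress, metabolism and protein synthesis.

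The rule names, for each age comparison, up to 10 passing genes each way with the largest change, non-overlapping groups and a mean of at least 5 CPM. Where fewer than 5 pass, the smallest p fill the number to 5, described as not passing. For the difference and for Paneth minus stem it names 5 each way, and for each list up to 4 members with the smallest p. Lgr5, Ascl2, Olfm4, Axin2, Wnt3, Notum, Lyz1, Cdkn1a and Mki67 are named always, with Defa24 and Mmp7 as check genes; predicted genes, clones and small RNAs are counted but not named. Single values per library were compared with exact two-sided permutation tests, adjusted over 5 tests. Ratios of genes with few reads in a group have exact binomial intervals at 95%, and groups with 0 reads were set to a floor of 3 reads over the group.

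Alternatives were other scalings (RLE size factors, library totals), no or a stricter count filter, DESeq2 1.42.0, limma-voom with sample weights (for the difference also with weights set per cell type), a test against a fold of 1.2, the replicate number as a block, all 13 libraries in the within-cell fits, Defa genes and Lyz1 left out, each library left out in turn, and fry or an estimated correlation for lists. After seeing the data 4 more were added: the enterocyte minus Paneth marker level as a covariate, 3 Paneth libraries left out together, the 3 loci left out before scaling, and the overlap with the stem fit without young stem 1.

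The fits were tested on simulated counts with 100 genes changed by a fold of 2 and 100 by a fold of 4. The stem fit recovered 51% and 94% of them and called 20 unchanged genes, the Paneth fit 1% and 54% with 3 unchanged genes, and the difference 0% and 24% with 1. Changes of a fold of 2 in Paneth cells are thus seldom detectable with these libraries. The changed genes had a mean of at least 5 CPM, and counts were drawn independently for each gene. The recovered shares thus do not cover differences between libraries that many genes share, such as those of young stem 1. Splicing, variants and reads outside the deposited genes were not analysed here. For some lists a member that the rule names is not reported here.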

Results

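RNA was sequenced from Paneth cells and intestinal stem cells of young mice (2 to 3 months) and aged mice (20 to 22 months). The labels describe male Lgr5 reporter mice on a mixed C57Bl6/SV129 background, in which Lgr5-positive stem cells carry green fluorescent protein. Cells came from crypts of the proximal small intestine after the villi had been removed. Paneth cells are the granular cells of the crypt base that secrete antimicrobial peptides and stand beside the stem cells. The study asks how Wnt signalling in both cell types changes with age. There were 4 young Paneth, 3 aged Paneth, 3 young stem and 3 aged stem libraries. The labels do not say whether replicates of a group came from separate animals, so the p-values below measure the spread between these samples, which may be technical. Paneth and stem libraries were made with different kits, so cell type and kit cannot be told apart.

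Library totals ran from 4606144 to 8424383 reads in young Paneth and from 4210439 to 8612228 reads in aged Paneth libraries. Stem libraries were deeper, with 8398966 to 19740104 reads in young and 13634957 to 16185549 reads in aged ones. Much of the Paneth depth lay on 3 loci, singled out after the files were read: Esp38 (chromosome 17, 39950520 to 39955287), Lars2 (chromosome 9, 123366927 to 123462675) and Gm20594 (chromosome 6, 79818031 to 79818364). They took 51.88% ± 9.99 (SD, n = 4) of reads in young Paneth and 32.23% ± 8.38 (SD, n = 3) in aged Paneth libraries. That difference gave p = 0.0286 in an exact two-sided permutation test, the smallest p that the 35 splits of 7 libraries allow, and 0.143 after adjustment over 5 such tests. In stem libraries their share was 6.12% ± 3.63 young and 8.41% ± 1.86 aged (SD, n = 3 each; exact permutation p = 0.4, smallest possible 0.1).

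Sex-linked genes, chosen after their values were seen, set 1 library apart. Values are CPM scaled by TMM over all 13 libraries. Xist, the X-chromosome RNA that is expressed in female cells (chromosome X, 103460373 to 103483233), stood at 12.65 CPM in young stem 1 and at 322 to 2880 CPM in the other 12 libraries. In young stem 1 the Y-chromosome genes stood at 44.0 CPM for Ddx3y, 35.0 for Uty, 22.7 for Eif2s3y and 59.0 for Kdm5d. The other 12 libraries held 0.639 to 3.32 CPM of Ddx3y and 0.14 to 1.58 CPM of Eif2s3y, although the labels call every mouse male.

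**Figure D1:**
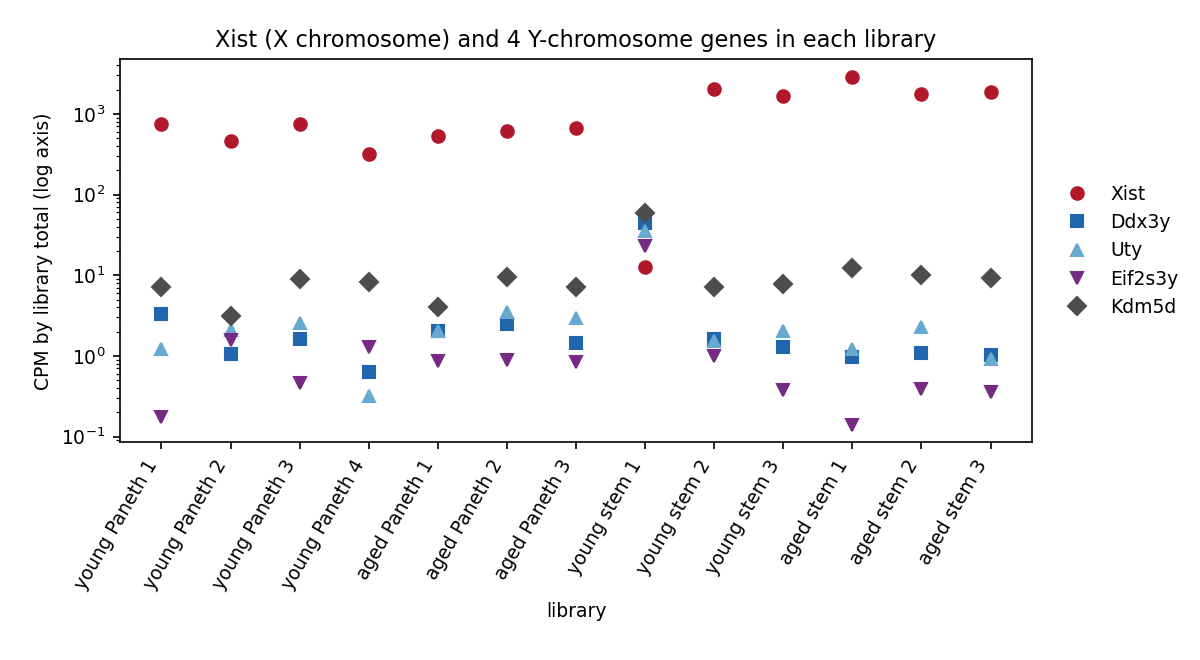
Xist and 4 Y-chromosome genes in the 13 libraries, with a point for each gene in each library. Values are CPM on a log axis, TMM-scaled over all 13 libraries although the axis label names the library total. Xist stands at 12.65 CPM in young stem 1 and at 322 to 2880 CPM in the other 12 libraries.

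In stem cells no single gene passed the test between aged and young mice; the genes below were among those with the smallest p. Chga (chromogranin A, a protein of enteroendocrine granules; Entrez 12652, chromosome 12, 102554941 to 102565027) stood at 28.1 ± 1.8 CPM in young and 124 ± 55.1 CPM in aged libraries, a log2 change of 2.14 ± 0.28 (SE; adjusted p = 0.0767). Ly6e, an interferon-inducible surface protein (Entrez 17069, chromosome 15, 74955025 to 74959904), stood at 53.8 ± 15.8 and 166 ± 12.2 CPM (1.62 ± 0.22; adjusted p = 0.0767). Amotl1, a junction protein that binds the coactivator Yap (Entrez 75723, chromosome 9, 14541966 to 14662974), stood at 20.8 ± 4.4 and 6.07 ± 0.74 CPM (-1.78 ± 0.24; adjusted p = 0.0767). Col1a2, a chain of type I collagen (Entrez 12843, chromosome 6, 4505618 to 4541543), stood at 20.0 ± 9.78 and 2.67 ± 0.80 CPM (-2.88 ± 0.43; adjusted p = 0.106). For each of these genes all 3 aged libraries lay on the same side of all 3 young libraries, which chance gives for 10% of genes. As the genes were picked for a small p, this separation adds no support.

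Other genes with the smallest p in aged stem cells were Itgae, the integrin αE chain (log2 change 1.78, adjusted p = 0.0767), Anks6 (1.90, 0.0938) and Amigo2 (2.05, 0.106) on the higher side. On the lower side they were Me1, the cytosolic malic enzyme (-1.84, 0.134), the amino acid transporter gene Slc38a4 (-1.64, 0.16) and Bgn, a matrix proteoglycan (-1.92, 0.16). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 17701 genes passed, the smallest adjusted p being 0.0767, while 1477 genes had an unadjusted p under 0.05. DESeq2 called 123 genes and limma-voom 1154. The count depended on single libraries: 1332 genes passed without young stem 1 and 46 without young stem 3. Young stem 1 also stood apart on the first principal component of the stem libraries, at -70.9 against -3.82 to 33.2 for the other 5, a component that held 35.4% of the variance.

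**Figure D2:**
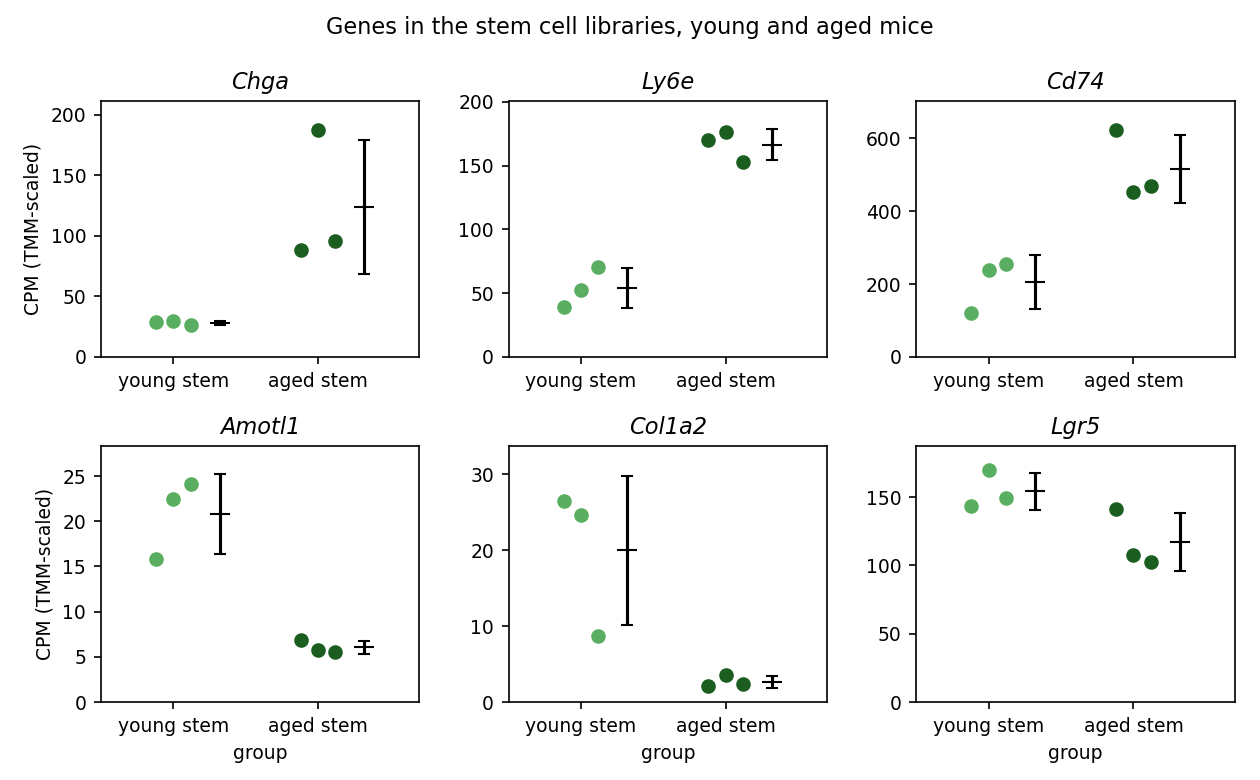
CPM of 6 genes in the stem cell libraries on linear axes from 0, with a point per library and bars for the mean ± SD of 3 libraries. Chga, Ly6e and Cd74 lie higher in each aged than in each young library, and Amotl1, Col1a2 and Lgr5 lower.

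Of 36 gene lists tested in stem cells, 14 passed by camera with its preset correlation, 6 higher and 8 lower in aged mice, and none with an estimated correlation (smallest adjusted p = 0.182). Antigen presentation genes rose as a list: 17 of 20 members were higher, with a median log2 change of 0.64 (adjusted p = 2.2e-15, or adjusted p = 0.182 with an estimated correlation). No member passed over all genes and 8 passed, all higher, when adjusted over the list alone. Among them were the immunoproteasome subunit Psmb8 (44.5 and 108 CPM; adjusted p = 0.158), the invariant chain Cd74 (205 ± 73.7 and 516 ± 93.9 CPM; adjusted p = 0.262) and the class II genes H2-Ab1 (1.34 ± 0.28 log2) and H2-DMb1 (1.61 ± 0.35 log2).

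Enteroendocrine markers rose in aged stem libraries, with 16 of 18 members higher, a median of 0.99 (adjusted p = 3.84e-15, or adjusted p = 0.403 with an estimated correlation), and 10 higher and 1 lower member passing when adjusted over the list alone. Beside Chga they included Chgb (1.77), the serotonin synthesis enzyme gene Tph1 (1.68) and the tachykinin precursor Tac1 (1.74). Goblet markers rose as well (12 of 13 higher, median 0.41, adjusted p = 7.21e-05, or adjusted p = 0.676 with an estimated correlation). Adjusted over the list alone, 2 of them passed, and Tff3, a mucosal trefoil peptide, stood at 0.92 and Spink4 at 0.72 on the log2 scale. Tuft cell markers rose by a median of 0.39 (11 of 13 higher, adjusted p = 0.0171, or adjusted p = 0.709 with an estimated correlation). The tuft call was lost without young stem 2 (0.121), young stem 3 (0.168), aged stem 2 (0.28) or aged stem 3 (0.146).

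Stromal markers fell in aged stem libraries: all 11 members were lower (median -1.8, adjusted p = 1.87e-11, or adjusted p = 0.484 with an estimated correlation), and 6 passed when adjusted over the list alone. Type I collagen Col1a1 stood at 27.8 ± 23.2 and 0.52 ± 0.11 CPM and the matrix protein Sparc at 10.97 ± 7.66 and 0.64 ± 0.32 CPM. Myeloid markers fell by a median of -0.58 (adjusted p = 0.032, or adjusted p = 0.676 with an estimated correlation) and pan-leukocyte markers by -0.50 (adjusted p = 0.00783, or adjusted p = 0.676 with an estimated correlation). Both calls were lost without young stem 1 (myeloid 0.578, leukocyte 0.221) or young stem 2 (myeloid 0.163, leukocyte 0.188). Yap targets fell (9 of 13 lower, median -0.33, adjusted p = 6.32e-05, or adjusted p = 0.182 with an estimated correlation), with 4 lower members passing when adjusted over the list alone, among them Amotl1, Cyr61 (-0.58) and the receptor tyrosine kinase gene Axl (-1.64).

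Among genes of the Wnt pathway and stem cell identity, none passed with all 6 stem libraries, and some passed without young stem 1. Lgr5, the R-spondin receptor that marks these cells (Entrez 14160, chromosome 10, 115450314 to 115587780), stood at 154 ± 13.7 CPM in young and 117 ± 21.2 CPM in aged libraries (-0.40 ± 0.18 log2, adjusted p = 0.588). The transcription factor gene Ascl2 stood at 54.8 and 43.6 CPM (-0.33, 0.624), and Olfm4 at 4586 ± 322 and 4200 ± 1359 CPM (-0.13, 0.91). The negative feedback gene Axin2 stood at 461 ± 100 and 463 ± 24.9 CPM (0.01, 0.996). Wnt target genes fell as a list by camera (15 of 22 lower, median -0.20, adjusted p = 0.023, or adjusted p = 0.676 with an estimated correlation). Intestinal stem cell markers fell too (21 of 25 lower, median -0.11, adjusted p = 0.0202, or adjusted p = 0.676 with an estimated correlation). The lists share Lgr5, Ascl2, Axin2, Sox9, Nkd1, Rnf43, Znrf3, Ephb2, Ephb3 and Tnfrsf19, so they are not separate results. With all 6 libraries no member of either list passed over all genes or when adjusted over the list alone. Without young stem 1, 4 Wnt targets passed over all genes, with Ccnd2 (-0.94, adjusted p = 0.00471), Ccnd1 (-0.80, 0.0102) and Tnfrsf19 (-0.70, 0.0292) lower and Myc higher (0.57, 0.0291), as did 2 stem markers, Tnfrsf19 and Msi1 (0.77, 0.0201). In that fit 4 Wnt receptor or pathway genes passed too, 3 higher and 1 lower, among them Bcl9l (0.86, 0.0152), Bcl9 (0.85, 0.0226) and Lgr4 (-0.63, 0.0156), while Lgr5 (-0.42, 0.131) and Ascl2 (-0.27, 0.332) did not. Young stem 1 lay nearer to the aged mean than to young stem 2 and 3 in all 4 of these Wnt targets. The same held for all 4 receptor or pathway genes and the 2 stem markers. These calls thus separate young stem 2 and 3 from the aged libraries, not all young libraries. The Wnt target call was lost without young stem 1 (0.133), young stem 3 (0.108), aged stem 2 (0.0729) or aged stem 3 (0.12). The stem marker call was lost without young stem 1 (0.306), young stem 3 (0.118) or aged stem 2 (0.227). Wnt ligands, Wnt receptors and secreted Wnt antagonists gave adjusted p of 0.324, 0.696 and 0.618.

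Other lists passed in stem cells with medians nearer to 0 than the enteroendocrine, stromal or antigen presentation lists. Enterocyte markers fell by a median of -0.28 (adjusted p = 0.00234, or adjusted p = 0.676 with an estimated correlation; 0.0655 without young stem 1 and 0.526 without aged stem 1). Fatty acid oxidation genes fell by -0.14 (adjusted p = 0.0134, or adjusted p = 0.676 with an estimated correlation), with the dehydrogenase gene Acadl at -0.85. That call was lost without young stem 1 (0.0969), young stem 3 (0.167) or aged stem 1 (0.36). Antimicrobial genes rose by 0.18 (adjusted p = 0.0202, or adjusted p = 0.676 with an estimated correlation), a call lost without young stem 2 (0.0772), young stem 3 (0.158), aged stem 1 (0.148) or aged stem 2 (0.0729). Histone genes rose by 0.13 (adjusted p = 0.00958, or adjusted p = 0.792 with an estimated correlation), a call lost without young stem 2 (0.958), aged stem 2 (0.969, direction reversed) or aged stem 3 (0.067). The cell cycle inhibitor gene Cdkn1a stood at 0.44 ± 0.23 log2 (adjusted p = 0.626) and the proliferation marker Mki67 at -0.07 ± 0.25 (adjusted p = 0.955).

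Without young stem 1, 811 genes rose and 521 fell in aged stem cells among 18275 tested. In all 1332 the aged libraries did not overlap young stem 2 and 3. Genes that pass are picked for separated groups, so this adds no support to the calls. For genes not picked by the test, chance gives 20% for 3 against 2. Tnf, the inflammatory cytokine (Entrez 21926, chromosome 17, 35199367 to 35202007), rose by 2.88 ± 0.27 log2 (3.83 to 28.0 CPM, adjusted p = 7.92e-05) and the chemokine gene Cxcl10 by 2.25 ± 0.40 (adjusted p = 0.00574). The clock output genes Tef (-1.86 ± 0.16, adjusted p = 2.32e-05) and Dbp (-1.79 ± 0.32, adjusted p = 0.00567) fell. Chga (2.18), Anks6 (2.07), Itgae (1.99), Tph1 (1.96), Amotl1 (-1.91), Me1 (-1.95) and Col1a2 (-2.61) passed in this fit. Antigen presentation genes (adjusted p = 2.32e-09) and enteroendocrine markers (adjusted p = 8.89e-07) rose in it by camera, with adjusted p = 0.811 for both with an estimated correlation.

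In aged Paneth cells, 2 genes fell and none rose. Mptx2, a mucosal pentraxin (Entrez 100504232, chromosome 1, 173274461 to 173277756), fell from 454 ± 267 CPM (SD, n = 4) to 3.66 ± 1.42 CPM (SD, n = 3), a log2 change of -6.97 ± 0.73 (SE; adjusted p = 0.039). Rps4y2, a gene similar to that of ribosomal protein S4 (Entrez 66184, current symbol Rps4l, chromosome 6, 148354656 to 148355596), fell from 12.2 ± 4.02 to 0.19 ± 0.18 CPM (adjusted p = 0.0443). The 4 young libraries held 237 Rps4y2 reads and the 3 aged ones 5, a ratio of 54 (95% interval 22.8 to 168, exact binomial, which like all intervals here covers counting error only). For both genes all 3 aged libraries lay below all 4 young ones, and groups of 3 and 4 separate by chance for 5.71% of genes. Since the test picked both genes, this separation adds no support. Reads of Mptx2 can be shared with its paralog Mptx1 and those of Rps4y2 with other S4 genes, so both values are uncertain to that extent.

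Close to the threshold in Paneth cells were Mptx1 (72.6 ± 48.4 to 0.83 ± 0.58 CPM, -6.58 ± 0.82 log2), Tm7sf2, which encodes a sterol reductase (145 ± 112 to 4.41 ± 1.25 CPM, -5.05 ± 0.65), and the homeobox gene Hhex (42.2 ± 27.9 to 2.22 ± 0.48 CPM, -4.25 ± 0.55). Each had an adjusted p of 0.0539 and all 3 aged libraries below all 4 young ones. Higher in aged Paneth cells, without passing, were Pcp4l1 (3.85, adjusted p = 0.126), the clock output gene Dbp (4.54 ± 1.33 to 17.9 ± 2.37 CPM, 1.98, 0.163), Akr1c19 (3.76, 0.176), the tissue factor gene F3 (2.74, 0.188) and Retsat, a retinol saturase (2.40, 0.232). By edgeR 2 of 14106 genes passed, 1189 had an unadjusted p under 0.05, and DESeq2 called 114 and limma-voom 1748. With scaling by library totals, which moved the median of all genes by 0.573, 12 genes passed and 50% of them were higher. The calls rest on single libraries: none passed without young Paneth 1 or 3 or aged Paneth 2 or 3, 2 other genes (Tm7sf2 and Hhex) without young Paneth 2, 6 without young Paneth 4 and 20 without aged Paneth 1.

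Paneth cell markers fell in aged Paneth libraries: all 24 members were lower (median -1.71, adjusted p = 1.18e-23, or adjusted p = 0.417 with an estimated correlation), 1 of them (Mptx2) passed over all genes and 7 when adjusted over the list alone. Single members varied widely between libraries. Lysozyme (Lyz1; Entrez 17110, chromosome 10, 117287795 to 117292868) stood at 10560 ± 7453 CPM in young and 3567 ± 3382 CPM in aged libraries (-1.57 ± 0.96, adjusted p = 0.658). The defensin gene Defa24 stood at -1.49 (0.663) and the matrix metalloproteinase gene Mmp7, whose product activates defensins, at -2.33 ± 0.77 (0.534). Antimicrobial genes also fell (11 of 14 lower, median -1.4, adjusted p = 2.59e-05, or adjusted p = 0.152 with an estimated correlation), 5 lower and 2 higher members passing when adjusted over the list alone. This list shares Reg3g, Ang4, Pla2g2a and Itln1 with the Paneth markers, so the falls are in part the same. The lectin gene Reg3g stood at 47.8 ± 8.24 and 3.41 ± 3.37 CPM (adjusted p = 0.232), the nitric oxide synthase gene Nos2 at 24.6 ± 12.7 and 1.30 ± 0.90 CPM (adjusted p = 0.146), and Reg1 at 2.10 log2 (adjusted p = 0.505).

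Enterocyte markers rose at the same time in aged Paneth libraries: 19 of 20 members were higher (median 1.24, adjusted p = 1.57e-09, or adjusted p = 0.637 with an estimated correlation), and none passed over all genes or when adjusted over the list alone. Examples were Cyp3a11 (44.8 ± 25.5 to 446 ± 467 CPM) and the apolipoprotein gene Apoc3 (17.7 ± 14.4 to 90.4 ± 58.3 CPM). Peroxisome proliferator and fatty acid oxidation genes rose (23 of 24 higher, median 0.98, adjusted p = 1.22e-11, or adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 1 passed. Among them Acot1, an acyl-CoA thioesterase gene, stood at 2.60 on the log2 scale. The enterocyte level minus the Paneth marker level, in mean log2 CPM, was -2.3, -3.84, -2.33 and 2.41 in the 4 young libraries and 0.02, 4.63 and 3.31 in the 3 aged ones. Their means of -1.51 ± 2.71 and 2.65 ± 2.37 gave p = 0.0857 in an exact two-sided permutation test over 35 splits and 0.143 after adjustment over 5 tests.

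**Figure D3:**
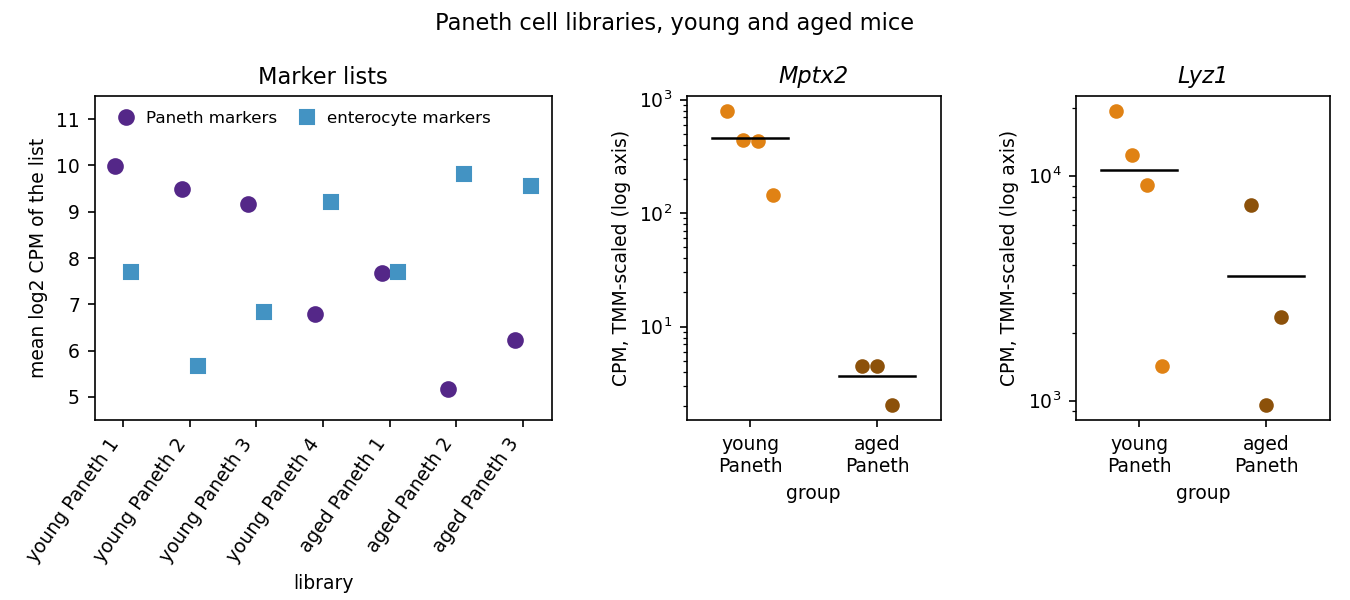
Left, mean log2 CPM of the Paneth and enterocyte marker lists in each Paneth library; middle and right, Mptx2 and Lyz1 in CPM on log axes, with a point per library and a line at the group mean. Mptx2 lies at 144.2 to 797.3 CPM in young and at 2.02 to 4.49 CPM in aged libraries, whereas Lyz1 overlaps between the groups.

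Histone genes fell in aged Paneth libraries: 52 of 53 members were lower (median -1.28, adjusted p = 4.77e-30, or adjusted p = 0.417 with an estimated correlation) and 19 passed, all lower, when adjusted over the list alone. Examples were Hist1h2bm (6.93 ± 1.71 to 1.13 ± 0.38 CPM) and Hist1h2bn (11.97 ± 2.62 to 2.63 ± 1.29 CPM); histone genes are near-identical copies that can share reads. Cell cycle genes fell (28 of 30 lower, median -0.85, adjusted p = 5.58e-09, or adjusted p = 0.594 with an estimated correlation), with the topoisomerase gene Top2a at -1.39 and the cyclin gene Ccnb1 at -2.003. Goblet markers fell (11 of 12 lower, median -1.07, adjusted p = 8.2e-05, or adjusted p = 0.594 with an estimated correlation), including Agr2 (-2.12) and Spink4 (-2.29), but turned higher without passing (0.744) when the enterocyte minus Paneth marker level entered as a covariate, an alternative chosen after seeing the data. Ribosomal protein genes fell slightly (73 of 76 lower, median -0.29, adjusted p = 0.000743, or adjusted p = 0.753 with an estimated correlation), a call lost without young Paneth 3 (0.115) or aged Paneth 2 (0.247). Scaling by library totals, which shifts all genes upward, put 71 of the 76 higher, and the list stayed lower against the other genes (0.00483). The list turned higher with that covariate (9.46e-11) and, without passing, when the 3 libraries of high enterocyte level were left out (0.925). Unfolded protein response genes fell (19 of 22 lower, median -0.32, adjusted p = 0.00175, or adjusted p = 0.637 with an estimated correlation), with the disulphide isomerase gene Pdia6 at -1.43, while 16 of 22 were higher under scaling by library totals, where the list stayed lower against the other genes (0.00751).

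For Wnt signalling in Paneth cells, the ligand gene Wnt3 stood at 11.9 ± 5.36 CPM in young and 8.48 ± 8.93 CPM in aged libraries (-0.54 ± 0.67 log2, adjusted p = 0.825). Notum, a secreted enzyme that removes a lipid from Wnt proteins (Entrez 77583, chromosome 11, 120653788 to 120661193), stood at 1.52 ± 1.02 and 3.92 ± 1.84 CPM (1.44 ± 0.72, adjusted p = 0.62). The receptor gene Fzd3 stood at -1.29 ± 0.38 (adjusted p = 0.528) and Wnt10b at -1.23 ± 0.46 (adjusted p = 0.555). Wnt target genes fell as a list (19 of 22 lower, median -0.40, adjusted p = 0.00722, or adjusted p = 0.694 with an estimated correlation). Stem cell markers, which share many genes with the Wnt targets, fell too (22 of 25 lower, median -0.44, adjusted p = 0.00392, or adjusted p = 0.694 with an estimated correlation), with no member passing in either. The Wnt target call was lost without young Paneth 2 (0.0501), young Paneth 3 (0.082), aged Paneth 2 (0.357) or aged Paneth 3 (0.05). The stem marker call was lost without young Paneth 3 (0.0682) or aged Paneth 2 (0.357). Both lists turned higher when the enterocyte minus Paneth marker level entered as a covariate (Wnt targets 2e-05, stem markers 7.19e-08), an alternative chosen after seeing the data. Wnt ligands, Wnt receptors and secreted Wnt antagonists gave adjusted p of 0.664, 0.312 and 0.423 in Paneth cells; for the receptors the median was 0.04, the mean -0.20 and the test's direction lower. Cdkn1a stood at 0.21 log2 (adjusted p = 0.85) and Mki67 at -0.99 ± 0.47 (adjusted p = 0.602). With scaling by library totals, which shifts all genes upward, 13 of 22 Wnt targets and 14 of 25 stem markers were higher, and both lists stayed lower against the other genes (0.002 and 0.000479).

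Interferon response genes (median -0.47, adjusted p = 0.00308) and DNA repair genes (-0.37, adjusted p = 0.00392) fell in aged Paneth libraries, and genes of the epidermal growth factor pathway rose (0.24, adjusted p = 0.041). Under scaling by library totals 14 of 24 interferon and 16 of 25 repair genes were higher, although both lists stayed lower against the other genes (0.000263 and 0.00239), and the growth factor call was lost (0.0611). With the enterocyte minus Paneth marker level as a covariate the repair list turned higher without passing (0.506). The 3 lists gave adjusted p = 0.694, adjusted p = 0.694 and adjusted p = 0.417 with an estimated correlation. The interferon call was lost without young Paneth 4 (0.616) or aged Paneth 1 (0.302), the repair call without young Paneth 3 (0.0587) or aged Paneth 2 (0.0917), and the growth factor call without young Paneth 1 (0.0769), young Paneth 4 (0.114) or aged Paneth 3 (0.147).

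The age change of Paneth cells minus that of stem cells asks whether both cell types age alike. Among the genes with the smallest p, the age change was lower in Paneth than in stem cells for Mptx2 (-6.06 ± 0.84, adjusted p = 0.0512), Tm7sf2 (-4.71 ± 0.69, 0.0512), Hhex (-4.18, 0.0645) and Atoh8 (-6.21, 0.0645), and higher for Dbp (3.47 ± 0.57, 0.0703), Amotl1 (1.82 ± 0.34, 0.103) and Col1a2 (2.81 ± 0.53, 0.103). Tnf stood lower too (adjusted p = 0.0703): it held 113 reads in the 4 young Paneth and 3 reads in the 3 aged Paneth libraries, a ratio of 43.3 (95% interval 14.4 to 213). None of 16960 genes passed by edgeR, 1493 had an unadjusted p under 0.05, and DESeq2 called 100 and limma-voom 2251, or 0 with its weights set per cell type. The count was 90 without aged Paneth 1, 27 without young Paneth 4, 17 without young stem 1, 6 without young stem 3, 4 without young Paneth 2 and 2 without aged stem 3, and 15 (66.7% higher) with scaling by library totals, which moved the median of all genes by 0.592.

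By list, the age change was lower in Paneth than in stem cells for histone genes (62 of 64 members, median -1.53, adjusted p = 1.13e-28, or adjusted p = 0.292 with an estimated correlation; 26 passing when adjusted over the list alone). It was lower too for Paneth markers (24 of 24, -1.7, adjusted p = 1.16e-13, or adjusted p = 0.357 with an estimated correlation; 5 passing when adjusted over the list alone) and goblet markers (13 of 13, -1.52, adjusted p = 3.54e-08, or adjusted p = 0.292 with an estimated correlation). Enteroendocrine markers (-1.32, adjusted p = 3.39e-05) and antigen presentation genes (-0.83, adjusted p = 0.000119) were also lower, with adjusted p = 0.55 and adjusted p = 0.682 with an estimated correlation. The antigen presentation call was lost without young Paneth 4 (0.127) or aged Paneth 1 (0.0938). The change was higher for stromal markers (10 of 10, 2.01, adjusted p = 1.38e-08, or adjusted p = 0.287 with an estimated correlation), enterocyte markers (19 of 20, 1.6, adjusted p = 9.22e-10, or adjusted p = 0.51 with an estimated correlation) and fatty acid oxidation genes (23 of 24, 1.18, adjusted p = 3.26e-12, or adjusted p = 0.292 with an estimated correlation). Lgr5 (-0.04, adjusted p = 0.988), Wnt3 (-0.92 ± 0.81, 0.737) and Notum (1.22 ± 0.91, 0.696) did not pass.

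No gene was called in the same direction with age in both cell types, 0 genes being called in stem cells among the 13982 tested in both. Rps4y2 was the 1 gene lower in both when young stem 1 was left out, against 0.0705 expected by chance (Fisher's exact test p = 0.0692). Across those genes, which are not independent replicates, Spearman's rho of the age changes was -0.0417 with all libraries and -0.116 without young stem 1.

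Paneth libraries differed from stem libraries at both ages, and most markers of each type lay in the direction of the cell type labels. In young mice Lyz1 stood at 14650 ± 10610 CPM in Paneth and 591 ± 128 CPM in stem libraries (4.63 ± 0.90 log2, adjusted p = 0.001), Defa24 at 4.54 (0.000965) and Mmp7 at 3.48 (0.00117). Lgr5 fell by 1.54 on the log2 scale from stem to Paneth (105 and 36.1 CPM, adjusted p = 0.00272), Ascl2 by 2.13 (0.00118) and Olfm4 by 2.16 (0.00176). In aged mice Lyz1 was 3.04 higher (adjusted p = 0.0101; 0.0547 without aged Paneth 1 and 0.0519 without aged stem 3), Defa24 3.15 higher (0.00756), and Mmp7 stood at 1.35 (0.113). The stem genes were lower again (Lgr5 -1.58, adjusted p = 0.00416; Ascl2 -2.46, 0.000931; Olfm4 -2.67, 0.000893). Paneth markers rose with medians of 4.9 (24 of 24 members passing over all genes and over the list alone; adjusted p = 2.72e-11) in young and 2.98 (17 higher, 2 lower, or 19 and 2 when adjusted over the list alone; adjusted p = 0.00274) in aged mice, or adjusted p = 0.438 and adjusted p = 0.685 with an estimated correlation.

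Paneth cell niche factors did not pass as a list in young (adjusted p = 0.059) or aged mice (0.114), nor did Wnt ligands (0.0728 and 0.239), although single genes did. Wnt3 stood 2.45 ± 0.59 higher in young Paneth than in young stem cells (adjusted p = 0.00399) and 1.53 ± 0.60 in aged mice (0.0509). Wnt7b stood 5.41 (0.000417) and 4.98 (0.00066) higher, and the Wnt antagonist genes Kremen1 5.35 (2.31e-05) and 4.52 (6.71e-05) and Dkk2 3.01 (2.24e-05) and 3.36 (1.2e-05). Notum was 1.87 higher in young mice (adjusted p = 0.0368) and 3.08 higher in aged mice (adjusted p = 0.00159). The young call for Notum was lost without young Paneth 2 (0.083), 3 (0.142) or 4 (0.0578) or young stem 1 (0.0978), 2 (0.0688) or 3 (0.0799). Secreted Wnt antagonists rose as a list (medians 0.95 and 1.19; adjusted p = 0.00289 and 0.00452, or adjusted p = 0.316 and adjusted p = 0.38 with an estimated correlation). Cdkn1a was 2.46 ± 0.29 (2.15e-05) and 2.23 ± 0.29 (4.92e-05) higher. Axin2 did not pass in either age group (-0.42, 0.491; -0.98, 0.126). Mki67 stood at -0.44 (0.395) in young mice and was lower in Paneth cells of aged mice (-1.38, 0.0188), a call lost without aged Paneth 2 (0.0832), aged Paneth 3 (0.0572) or aged stem 3 (0.0612). The difference of its age change between the cell types did not pass (-0.94, adjusted p = 0.645).

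In young mice Nkx6-1, a homeobox gene (Entrez 18096, chromosome 5, 101659184 to 101664711), held 536 CPM in Paneth and 0.41 CPM in stem libraries (10.62 ± 0.84 log2, adjusted p = 1.1e-06) and Cabp1, a calcium-binding protein gene, 319 and 0.19 CPM (10.61 ± 0.67, 2.46e-07). Ankrd2 held 2237 reads in the 4 young Paneth and 2 in the 3 young stem libraries, a ratio of 4900 (95% interval 1350 to 40500), and Olfr1243 held 1015 and 2, a ratio of 2220 (613 to 18400). Ankrd63 stood 10.40 ± 1.04 higher. Lowest in young Paneth cells were Bmper (-7.47 ± 0.74), Znrf1 (-7.06 ± 1.06), Hist1h2ap (2134 reads in stem, 5 in Paneth, ratio 97.5, 41.7 to 301), Trap1a (-6.26) and Hist1h4n (-6.11). In aged mice Nkx6-1 (10.82 ± 0.86), Cabp1 (9.55 ± 0.64), the apolipoprotein gene Apoa4 (8042 and 9.42 CPM, 9.74 ± 1.18) and Cyp3a11 (9.59 ± 1.13) were highest. Olfr1000 held 136 reads in aged Paneth and 0 in aged stem libraries, so it was at least 168-fold higher with a floor of 3 reads over the group. Hist1h2ap (4 reads in Paneth, ratio 190, 74.2 to 699), Hist1h2bq (-6.87 ± 0.50), Tnf (1191 reads in stem, 3 in Paneth, ratio 107, 36.6 to 521), Hist1h4n (-6.00) and Hist2h2aa2 (-5.98) were lowest.

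By list, ribosomal protein genes were lower in Paneth libraries at both ages (66 of 77 passing in young and 72 in aged mice, medians -1.83 and -2.15; adjusted p = 1.8e-27 and 2.05e-31, or adjusted p = 0.38 for both with an estimated correlation). Histone genes (-1.84 and -3.33; 1.79e-12 and 3.08e-29), cell cycle genes (-1.71 and -2.2; 2.1e-08 and 5.56e-13), DNA repair genes (-1.42 and -1.65) and nuclear oxidative phosphorylation genes (-1.11 and -0.97) were lower too. Intestinal stem cell markers fell by medians of -1.52 (18 of 25 members passing lower and 3 higher; adjusted p = 9.44e-05) and -1.7 (17 lower and 2 higher; 1.6e-05), or adjusted p = 0.64 and adjusted p = 0.685 with an estimated correlation. Enterocyte markers were higher in Paneth libraries at both ages (medians 3.95 and 5.44, with 17 and 19 of 20 members passing; adjusted p = 8.93e-07 and 2.25e-11, or adjusted p = 0.546 and adjusted p = 0.433 with an estimated correlation), as were enteroendocrine markers (2.63 and 1.37) and immediate early genes such as Fosb and Egr1 (1.12 and 1.07). No list held at either age with an estimated correlation, the smallest being adjusted p = 0.316 in young and adjusted p = 0.38 in aged mice.

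In young mice 6924 of 16960 genes passed, 3323 higher and 3601 lower in Paneth libraries, and in aged mice 7071, 3452 higher and 3619 lower. These counts hold the difference between kits as well as between cells. Scaling by library totals, which moved the median of all genes by -1.23 in young and -0.641 in aged mice, gave 11122 genes (1071 higher, 10051 lower) and 7906 genes (1798 higher, 6108 lower). Changes in this comparison are relative to that shift, which in young mice is larger than the medians of secreted Wnt antagonists (0.95) and immediate early genes (1.12).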

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

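The tests of young stem 2 and 3 standing apart, of a wrong age label, of the library scaling factors, of Mptx1 and Mptx2 against the other Paneth markers and of the clock genes were chosen only after the result was seen. Leaving out the loci that collect most reads was also chosen after seeing the data. The test of enterocyte RNA names libraries by their observed marker levels, so it too was built after these were seen. No order is claimed for the remaining tests.

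The first pattern is the set of 1332 genes that pass in aged stem cells without young stem 1, against 0 with it (edgeR; 1477 at an unadjusted p under 0.05, 123 by DESeq2, 1154 by limma-voom). With an aged library also left out, the count without young stem 1 was 751 (aged stem 1), 487 (aged stem 2) or 3104 (aged stem 3). The lower depth of young stem 1 is argued against, since 1328 genes passed without it when the other libraries were thinned to its 8398780 reads (its total after rounding per gene). In 84.2% of the 1332 genes young stem 1 lay nearer to the aged mean than to young stem 2 and 3, but this largely restates that it ends the calls, so whether those 2 libraries stand apart for a reason other than age stays open. A wrong age label of young stem 1 cannot be told apart from it: its share of genes nearer to young libraries was between 0.42 and 2.5 times that of held-out aged libraries (12.8%, 7.8% and 44.3%), so aged libraries themselves vary too much, and although it stood with the young libraries for Rps4y2 (48.6 CPM; aged 0.293 to 2.63), Chga (28.5; 88.2 to 187), Cd74 (120; 453 to 624) and Col1a2 (26.5; 2.07 to 3.58), and for 8 of 10 called antigen presentation genes, these genes were picked for their age difference and exclude nothing. Age as the cause of these calls was not tested and stays open. Young stem 1 was also the only stem library with low Xist (12.65 CPM, other 5 stem libraries 1673 to 2880). Its Ddx3y was high (44.0 CPM, others 0.98 to 1.62). Whether a difference in the sex or origin of young stem 1 accounts for the calls stays open too.

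The second pattern is the lower Paneth and higher enterocyte marker level in aged Paneth libraries. With library totals, which shift the median of all genes by 0.573, all 24 Paneth markers were lower and all 20 enterocyte markers higher. These opposite directions argue against scaling as the whole cause, because a scaling factor moves all genes alike. The camera test (larger adjusted p of the lists 2.94e-07) adds little. It compares a list with the other genes, so a shift common to all genes hardly changes it. Leaving out the 3 loci that collect most reads tests little, since it shifted all genes by 0.0146 (list medians at least 0.991 times those with them). RNA of enterocytes in young Paneth 4, aged Paneth 2 and aged Paneth 3 may explain part of it: across 14062 genes outside both lists, which are not independent replicates, the age change had r = 0.411 with young Paneth 4 minus young Paneth 1 to 3, between the bounds set for and against it, so it stays open; no sort or gate is named in the labels. Mptx1 lay -6.2 SD and Mptx2 -6.73 SD from the other 22 Paneth markers (mean -2.09, SD 0.725, lowest Reg3g at -3.75). These distances argue against a lower share of Paneth RNA alone for these genes. The argument is weakened because the genes were picked for large falls and can share reads, so they are not 2 separate results. A change of Paneth cells with age is open and untested.

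The third pattern is the opposite age change of clock genes. The median of Dbp, Tef, Hlf, Per, Cry and Nr1d genes minus that of Arntl, Npas2, Clock and Nfil3 was 1.53 in aged minus young Paneth cells and -2.04 in stem cells without young stem 1, or -1.38 with all 6 stem libraries, where no clock gene passed. Collection at different clock phases stays open: the genes were picked for these opposite signs, so the values are no test of it, and times of collection are not in the labels. Young stem 1 lay nearer to the aged mean in 11 of 14 clock genes, but these were picked with the fit that left it out, so the count is no test of age, which stays open.

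The 4 young Paneth libraries were compared in 56 values: library total, share of the 3 loci, named genes and 33 list levels. In 4 of the 56 a library lay far from the others by Dixon's test at its 95% limit. All 4 were list levels, and chance flags about 1 in 20. In young Paneth libraries, in mean log2 CPM, young Paneth 4 stood at 4.17 for intestinal stem cell markers (others 5.44 to 5.56) and at 4.25 for goblet markers (5.58 to 5.67). Young Paneth 1 stood at 2.39 for secreted Wnt antagonists (2.88 to 2.97), and young Paneth 3 at 3.96 for epidermal growth factor pathway genes (3.68 to 3.72).

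The age change differed between the cell types for 14 lists by camera (no list with an estimated correlation, smallest adjusted p 0.07). Lower in Paneth than in stem cells were histone genes (1.13e-28), Paneth markers (1.16e-13), goblet markers (3.54e-08), cell cycle genes (4.56e-06), antimicrobial genes (1.99e-05) and enteroendocrine markers (3.39e-05). Also lower were ribosomal proteins (8.39e-05), antigen presentation (0.000119), interferon response (0.00103), unfolded protein response (0.0197) and DNA repair genes (0.0224). Higher were fatty acid oxidation genes (3.26e-12), enterocyte markers (9.22e-10) and stromal markers (1.38e-08). With library totals the unfolded protein response (0.0623) and repair (0.0502) calls were lost, and with all genes shifted upward 54 of 77 ribosomal, 15 of 22 unfolded protein response and 17 of 25 repair genes were higher. Calls were lost for interferon genes without young Paneth 4 (0.197) or aged Paneth 1 (0.127), for antigen presentation genes without the same libraries (0.127, 0.0938), and for ribosomal proteins without aged Paneth 2 (0.0797). The unfolded protein response call was lost without young Paneth 1 (0.167), aged Paneth 1 (0.0988) or aged stem 3 (0.0543). The repair call was lost without young Paneth 3 (0.171), aged Paneth 2 (0.193), aged Paneth 3 (0.0616), young stem 1 (0.113) or aged stem 3 (0.101).

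Other splits of the same libraries were fitted as well. For stem cells the 10 splits are too few: the real one called 0 genes and the highest other 982 (a real count of 0 is reached by 10 of 10 whatever the data, so it tests nothing); for lists the values were 14 and 19, with 3 as large, and without young stem 1 they were 1332 and 60 genes, with 1 as large. The split with 982 genes sets young stem 1, aged stem 1 and aged stem 2 against the rest and points to a structure of the samples other than age. For Paneth cells chance cannot be excluded: 2 of 35 splits called as many as the real 2 genes and 12 as many as the real 14 lists, and the highest others called 2470 genes and 18 lists. The 2470 genes came from young Paneth 1 to 3 with aged Paneth 1 against the other 3 libraries, a structure of the samples that follows the enterocyte level. For the difference chance cannot be excluded for the lists, with 31 of 100 draws as large as the real 14 (highest 21); its real 0 genes (highest 1845) are reached by 100 of 100 draws whatever the data, which tests nothing. For Paneth minus stem in young mice only 1 of 35 splits, the real one with 6924 genes, was as large (highest other 2864). That is the lowest rank that 35 splits allow and is not adjusted over the tests of splits. It argues against chance without excluding it, and the real split also separates the library kits. In aged mice the 10 splits are too few (real 7071, highest other 0, 1 as large).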

How the results depend on the processing

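The fits with a marker covariate, without 3 Paneth libraries together, without the 3 loci and with the stem overlap lacking young stem 1 were chosen after seeing the data. Over all alternatives, 107 counts stayed within 1.5 times and 47 moved; for single genes and lists 2243 values kept direction and side of the threshold, 190 became stronger, 231 weaker and 51 reversed. The number of genes passing with age was most sensitive. In stem cells it was 0, but 11 with no count filter, 5 with all 13 libraries in the fit, 123 by DESeq2, 1154 by limma-voom and 0 to 1332 with a library left out (young stem 1 giving 1332 and young stem 3 giving 46). In Paneth cells it was 2, but 12 with library totals, 11 with no filter, 47 with all 13 libraries, 5 without the 3 loci, 7 with the covariate, 114 by DESeq2, 1748 by limma-voom and 0 to 20 with a library left out (20 without aged Paneth 1, 6 without young Paneth 4, 0 without young Paneth 1 or 3 or aged Paneth 2 or 3). For the difference it was 0, but 15 with library totals, 6 with no filter, 100 by DESeq2, 2251 by limma-voom (0 with weights per cell type) and 0 to 90 with a library left out (90 without aged Paneth 1, 27 without young Paneth 4, 17 without young stem 1). Paneth minus stem gave 11122 genes with library totals in young and 10688 by limma-voom in aged mice; leaving out a library gave 5163 to 6717 and 5410 to 7334. The cause was not tested.

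With the replicate number as a block, 15 genes passed in stem cells, 0 in Paneth cells and 8 in the difference. Deviations from the group mean of equally numbered libraries had correlations of 0.00738, -0.142 and 0.146 between young and aged stem libraries. Between young and aged Paneth libraries they were -0.0386, -0.391 and -0.11. Between stem and Paneth libraries they were -0.101, -0.0635 and 0.055 in young and 0.111, -0.0555 and 0.0641 in aged mice. These values show no pairing by number, but so few libraries cannot exclude it.

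The number of lists passing in stem cells was 14; it was 7 with all 13 libraries, 0 with an estimated correlation, 0 by directional and 2 by mixed fry, and 9 to 14 with a library left out. In Paneth cells it was 14, and 0, 0 and 2 by these 3 tests; in the difference it was 14, and 0, 0 and 5. Mixed fry asks another question than camera, and its calls are in part other lists. Without young stem 1, 1 gene was lower in both cell types, against 0.

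Directions turned mainly for genes near 0 change. In stem cells Lyz1 stood at -0.01948 with library totals, -0.03701 by limma-voom and -0.1518 with the replicate block. With a library left out the log2 ranges in stem cells were -0.34 to 0.13 for Olfm4, -0.12 to 0.22 for Axin2, -0.26 to 0.39 for Lyz1, -0.29 to 0.11 for Mki67, -0.40 to 0.30 for Defa24 and -0.43 to 0.0794 for Mmp7; for the difference they were -0.69 to 0.27 for Lgr5, -1.14 to 0.14 for Ascl2 and -0.37 to 0.0044 for Cdkn1a. Histone genes in stem cells had adjusted p from 1.29e-10 to 0.969, the last reversed. In Paneth cells Lgr5 stood at 0.0719 with library totals, against -0.41 in the main fit. In the difference Lgr5, Ascl2 and Cdkn1a stood at 0.48, 0.23 and 0.41 with library totals. That scaling shifts the median of all genes by 0.573 in Paneth cells and 0.592 in the difference, so these turns are no changes relative to other genes.

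With the covariate in Paneth cells Lgr5 (0.52), Ascl2 (0.55), Olfm4 (0.72), Axin2 (0.73), Wnt3 (0.82), Lyz1 (0.83), Defa24 (0.76) and Mki67 (0.0698) turned positive and Cdkn1a (-0.24) negative. Lyz1 and Defa24 are members of the Paneth list that enters the covariate, so their turn follows in part from its construction. Reversed lists had adjusted p of 2e-05 for Wnt targets, 7.19e-08 for stem markers, 0.744 for goblet markers, 0.506 for DNA repair, 9.46e-11 for ribosomal proteins and, by construction of the covariate, 0.00725 for enterocyte markers. Without the 3 libraries of high enterocyte level, which leaves 1 aged library assumed to vary like the young ones, Lgr5 (0.20), Ascl2 (0.13), Axin2 (0.14), Wnt3 (0.38) and Cdkn1a (-0.37) reversed, as did Wnt targets (0.885), stem markers (0.851) and ribosomal proteins (0.925). The cause was not tested beyond this. In simulated data the Paneth fit recovered 54% of genes changed by a fold of 4 and the stem fit 94%; the Paneth libraries have both fewer reads and a larger spread (0.406 against 0.246), and these were not separated.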

Other observations

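Some genes of the inflammatory response rose in aged stem cells when young stem 1 was left out, and several stood lower in aged Paneth cells; these genes, like the clock genes and Zfp91cntf, were chosen only after their values were seen. Without young stem 1, Tnf (2.88), Nfkbia (1.43, adjusted p = 0.00043), Nfkb2 (1.28, 0.000626), Tnip1 (1.26, 0.000626), Duox2 (1.93, 0.000157), Ltb (3.34, 0.00519) and Ccl20 (1.68, 0.00405) rose in aged stem cells. In aged Paneth cells Tnf stood at -5.17 ± 0.87 (0.176), Nos2 at -4.36 (0.146) and Duox2 at -4.99 (0.344), while Nfkb2 (-0.21, 0.85), Tnip1 (-0.24, 0.841) and Cxcl10 (0.32, 0.857) were near 0; none passed, and the list was not tested as a set. With all 6 stem libraries Tnf stood at 1.68 (0.588) and Nos2 at 0.60 (0.908). Young stem 1 stood above each aged stem library for Nfkb2 (74.2 CPM, young stem 2 and 3 23.29 and 21.35, aged 48.8 to 57.6). The same held for Tnip1 (72.35, 20.7 and 20.5, aged 45.7 to 52.6). For Tnf (13.2, 3.24 and 1.94, aged 15.5 to 20.4) it lay between them. These CPM are scaled over all 13 libraries. The rises are thus against young stem 2 and 3, not against all young libraries.

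Clock genes differed as well. Without young stem 1, Arntl (1.40, adjusted p = 0.000405), Npas2 (1.16, 0.00783) and Nfil3 (1.00, 0.00571) rose in aged stem cells and Tef (-1.86), Dbp (-1.79), Per2 (-1.21, 0.00141) and Nr1d2 (-1.10, 0.0013) fell. In aged Paneth cells Dbp (1.98, 0.163), Cry1 (1.32, 0.415) and Tef (1.22, 0.396) stood higher and Arntl lower (-0.60, 0.636), none passing.

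Rps4y2 fell in aged Paneth cells and, without young stem 1, in aged stem cells (-3.39 ± 0.57, adjusted p = 0.0196; 18.8 to 1.77 CPM). Young stem 1 held 48.6 CPM of it, young stem 2 and 3 held 18.0 and 19.4 and the aged stem libraries 0.293 to 2.63, and with all 6 it stood at -4.02 ± 0.70 (0.262). Zfp91cntf, whose locus overlaps Zfp91 so that reads may be assigned to either, stood at 39.3 CPM in young stem 1, 1.17 and 1.083 in young stem 2 and 3 and 29.8 to 35.03 in the aged stem libraries, and passed without young stem 1 (4.90 ± 0.26, 6.64e-08; 1332 genes passed in that fit).

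With the genes of X and Y left out, 0 genes passed in the stem comparison by edgeR. Genes are tested singly, so this says little about whether young stem 1 differs in sex or origin in ways that reach other chromosomes. Kdm5d and Uty stood at 3.16 to 12.18 and 0.319 to 3.55 CPM in the other 12 libraries. Without young stem 3, 46 genes passed. Those with the smallest p were the stromal genes Col3a1, Col1a1, Sparc and Col1a2, C1qa of the myeloid list, and Myh4, Tpm2 and Tnnt3. The last 3 are in neither list.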
